A study of Mus musculus with 35 samples.

How the data were processed

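Messenger RNA was measured by poly-A selected RNA sequencing of 35 mouse libraries. Per the labels, cells were infected with reprogramming factors and moved to the reprogramming medium iCD1, and some cultures received the growth factor BMP4 at 10 ng/ml from that medium change on. The factor combinations are labelled ODR, OA, OB, ODDR and ODB. The labels do not expand these names, and the series title and design text name Oct4, Kdm2b and the variant Polycomb complex PRC1.1. ODR, OA and OB were sampled at days 1, 6 and 14, ODR and OB also with BMP4 at day 6, and ODDR and ODB at day 9. A mouse embryonic stem cell (mESC) library and a mouse embryonic fibroblast (MEF) library complete the set.

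Per the submitters' processing notes, reads were handled with bcl2fastq, Bowtie2 2.2.5 and RSEM on genome build mm10. The deposited values are in a normalized tag count score per gene (unit: score), and the normalization step is not given in the sources used here. The table holds 21350 genes in 35 columns of whole numbers. Its columns share nearly the same distribution, with totals from 4255921 to 4398785 and a common ceiling of 18690 reached by 9 or 10 genes in each library and by 56 genes in any. These values are not read counts, so the depth per library is unknown and no counting interval is given. Where only 1 of the groups compared holds values at the ceiling, the size of the fold change is a lower bound, and where both do, it bounds nothing. A gene whose libraries of a group are all at 0 is reported as listed at 0. It is given no fold unless the text says that the fold rests on the 1 added before the log.

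There were 2 pairs of columns with identical values at all 21350 genes. ODR day 6 replicate 3 equals ODR with BMP4 day 6 replicate 2, and ODDR with BMP4 at day 9 equals ODB with BMP4 at day 9. The shared day 6 library was left out of both of its groups. This departs from the design fixed before the data were examined and leaves 2 ODR libraries without BMP4 and 1 with it. Fits that keep it under both or either label are among the alternatives. The shared day 9 library enters no test.

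Values were transformed as log2(value + 1), and genes with a value of at least 10 in at least 2 libraries were kept, which left 13860 genes. A single linear model with a mean for each of the 11 replicated groups was fitted with limma 3.58.1 in R 4.3.3 to 27 libraries, giving 16 residual degrees of freedom. Empirical Bayes moderation was used without trend or robust options. This is the fallback written for values that are not counts. The fit pools the spread over all groups, so a group with 1 library is assumed to vary like the others. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes of a comparison were called. There were 17 comparisons, 2 of them tests of a difference between effects (interactions). The labels do not say that a replicate number marks a batch, and the fit has no block. The origin of the replicates is not given, so the p-values measure the spread between libraries, which may be technical.

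The 25 gene lists were written before the data were examined. They are pluripotency, fibroblast and mesenchymal, epithelial, BMP pathway targets, primitive and extraembryonic endoderm, trophoblast, mesoderm, neural, Hox genes, PRC1.1 subunits and other Polycomb subunits. Further lists are p53 targets and Ink4 locus, senescence-associated secretory, cell cycle, germline, 2-cell-like, interferon response and glycolysis. The last 7 are keratinocyte, macrophage and leukocyte, endothelial, skeletal muscle and cardiac, adipocyte, chondrocyte, and immediate early and heat shock. A further pair of sets, 373 ESC-high and 781 MEF-high measured genes, differ by a log2 ratio of at least 3 between the mESC and MEF libraries, which enter no test. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Over the 425 pairs of list and comparison, 96 were called at the preset value and 2 with the estimated correlation. For the ESC-high and MEF-high sets these numbers were 21 and 7. Member counts are given over all genes tested and adjusted over the list alone. Fry p-values were computed as well and are not given.

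The text names Pou5f1 (Oct4), Kdm2b and Kdm2a in the comparisons of the factor combinations and of BMP4, and chooses other genes from those that a rule names. The rule takes the 6 largest changes in each direction among called genes whose libraries do not overlap (for interactions, among called genes) and whose higher group mean is at least 100. It also takes up to 3 members in each direction, by adjusted p, of each list called or with at least 3 called members. Predicted genes and clone names were left out, and some other genes that the rule names are not reported here. At day 9, with 1 library per label, log2 differences are given without a test, and list medians are set against 10000 random lists matched on size and expression. Gene locations are from GENCODE release M21 on the same build, where 21185 of the genes were found.

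Alternatives covered the pseudocount (0.1 and 10), the filter (none, and a minimum of 100), quantile normalization, median-of-ratios rescaling and limma's trend and robust options. They also covered fits of only the groups compared, a replicate block, a log2 fold change of at least 1 beside the adjusted p, and each library left out in turn. Chosen after seeing the data were the placement of the shared day 6 library, the removal of the library labelled OA day 14 replicate 2 and a correction for GC content and transcript length, known for 13825 genes (99.7%). The pipeline was tested on simulated data with 100 genes changed by a log2 value of 1 and 100 by 2 among 13860. The changed genes came only from those whose mean log2 value was at least that of a value of 100. Recovery of lower genes was therefore not tried. Noise was drawn independently for each gene, and the 30 cell cycle genes were also raised by a log2 value of 1. Between OB and ODR the pipeline recovered 79 and 97 at day 1, 84 and 100 at day 6, and 87 and 98 at day 14, with 8, 22 and 14 unchanged genes called. Between OA and ODR at day 14 it recovered 89 and 98, with 12 unchanged genes called. For BMP4 it recovered 57 and 95 in ODR and 79 and 97 in OB, with 13 and 20 unchanged genes called. Chromatin data of the study were not used here.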

Results

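The series holds RNA sequencing of mouse cells infected with factor combinations labelled ODR, OA and OB and grown in reprogramming medium. Cells were sampled at days 1, 6 and 14, and ODR and OB cells were also grown with BMP4 to day 6. The tests use 27 libraries: 2 per group at day 1, 2 ODR, 3 OA and 4 OB libraries at day 6, 3 per group at day 14, and 1 ODR and 2 OB libraries with BMP4. Another 6 labels have no replicate (ODDR and ODB at day 9 with and without BMP4, mESC and MEF), and the 2 with BMP4 at day 9 hold the same library. The comparisons ask how the OB and OA combinations differ from ODR and from each other at each day and how BMP4 changes ODR and OB at day 6. They also ask whether that change differs between them and how each combination changes from day 1 to day 14. Values are normalized tag counts, given as mean ± SD over the libraries of a group. Log2 fold changes carry ± SE from the limma fit, with Benjamini-Hochberg adjusted p-values.

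The label differences were visible in 2 paralogous genes. Kdm2b (chromosome 5, 122870665 to 122989823, minus strand), a histone H3K36 demethylase and PRC1.1 subunit, was at the ceiling of 18690 in every OB library of days 1 and 6 without BMP4. In the OB libraries of day 14 it was 4626, 6246 and 4220. In ODR it was 384 ± 107 at day 1, 254 ± 33.9 at day 6 and 262 ± 41.6 at day 14. Kdm2a (chromosome 19, 4314419 to 4398285, minus strand), the related demethylase, was at the ceiling in all OA libraries except OA day 1 replicate 2, at 9294, and the library labelled OA day 14 replicate 2, at 721. No library outside OA exceeded 1254. Pou5f1 (chromosome 17, 35506018 to 35510772, plus strand), which encodes the pluripotency factor Oct4, was at the ceiling in every library except OB day 14 replicate 1 (7086), mESC (3988) and MEF (0). Its fold changes between factor combinations are therefore not informative where both groups sit at the ceiling. The mESC library had 672 for Kdm2b and 478 for Kdm2a, and the MEF library had 287 and 868.

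**Figure D1:**
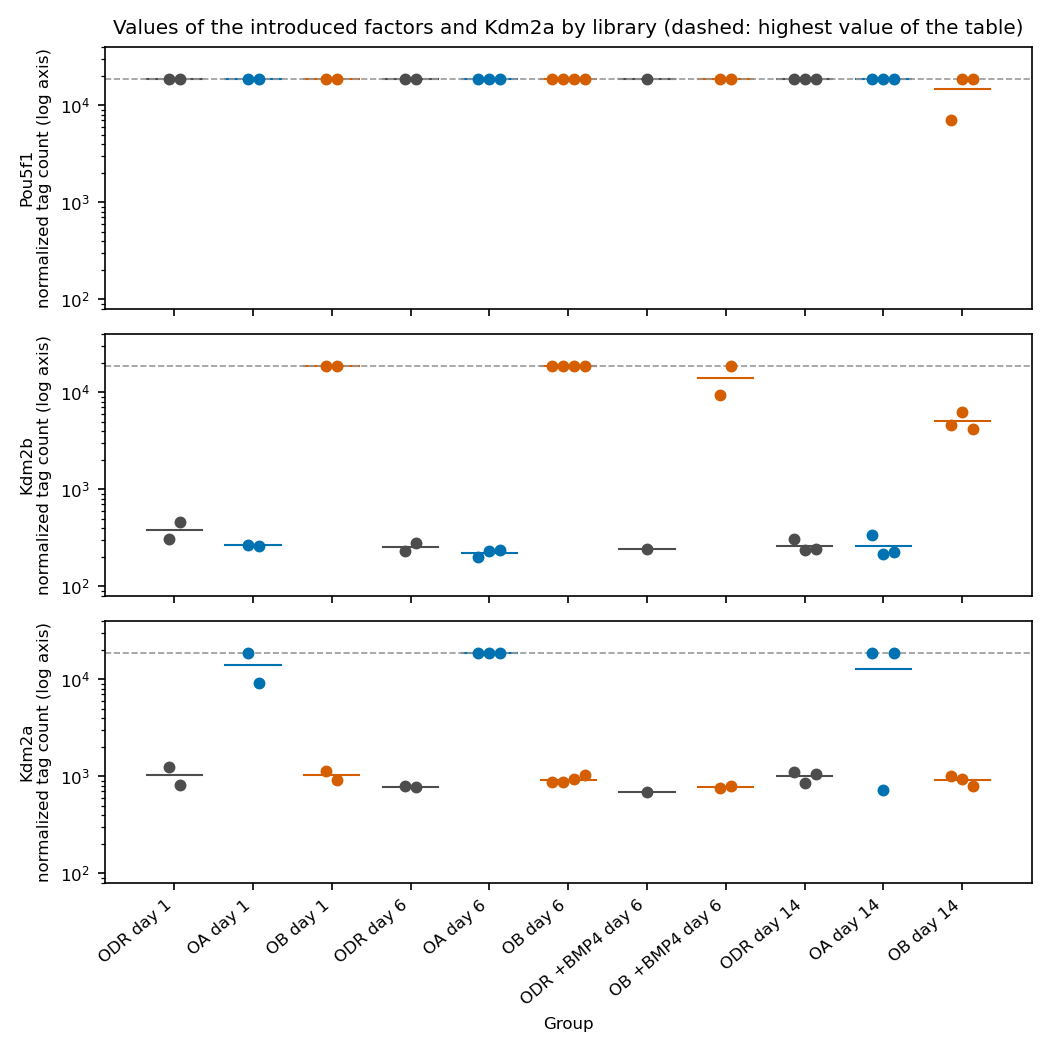
Normalized tag counts (log axis) of Pou5f1, Kdm2b and Kdm2a in each library, 1 point per library, grouped by label and day. Kdm2b is at the ceiling of 18690 in the OB libraries of days 1 and 6 without BMP4, Kdm2a is highest in OA, and the library labelled OA day 14 replicate 2 has a Kdm2a value of 721.

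At day 1, OB cells differed from ODR cells in 122 genes, with Kdm2b and Cyp26a1 among those that rose. Cyp26a1, which encodes an enzyme that degrades retinoic acid, rose from 0.5 ± 0.707 in ODR to 234 ± 65.1 in OB, a log2 fold change of 7.35 ± 0.55 (adjusted p = 7.32e-07, n = 2 and 2). Sox1, a transcription factor of neural progenitors, rose by 4.80 ± 0.76 (adjusted p = 0.00417) and Vgf, a neuropeptide precursor, by 3.05 ± 0.54 (adjusted p = 0.00807). Nefm, a neurofilament subunit, rose from 672 ± 274 to 3716.5 ± 1289. Cited1, a transcriptional coactivator, rose by 3.22 ± 0.61 (adjusted p = 0.0142). Prl8a6, a prolactin family gene, fell from 117 ± 7.07 to 58 ± 7.07, and Slc26a7, an anion exchanger, from 355 ± 1.41 to 72 ± 35.4. Kdm2b itself was higher by at least 5.63 ± 0.28, a lower bound because OB was at the ceiling, while Kdm2a differed by 0.01 ± 0.94 and Pou5f1 by 0.00.

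In all, 89 genes rose and 33 fell in OB at day 1. Neural genes rose as a list, with 3 of 18 measured members up and 0 down, the same 3 adjusted over the list alone (median log2 fold change 0.36, adjusted p = 0.011, and adjusted p = 0.185 with an estimated correlation). Interferon response genes fell as a list, with 0 of 26 up and 1 down (median -0.53, adjusted p = 0.000279, and adjusted p = 0.743 with an estimated correlation). ESC-high genes had 8 of 373 up and 0 down, 18 up and 3 down adjusted over the set alone (median 0.13, adjusted p = 0.00332, and adjusted p = 0.211 with an estimated correlation). The lists of BMP pathway targets (1 up, 0 down, median 0.39, adjusted p = 0.0142), endoderm (1 up, 0 down, median 0.23, adjusted p = 0.0435) and p53 targets (0 up, 0 down, median 0.13, adjusted p = 0.011) were also called upward. Their adjusted p with an estimated correlation was 0.743, 0.185 and 0.743. The count of 122 genes fell to 67 without ODR replicate 1, 28 without ODR replicate 2 and 16 without OB replicate 1. In a fit of only these groups limma called 0 genes, beside 1681 at an unadjusted p below 0.05. Vgf, Nefm, Slc26a7, Cited1 and Sox1 lost their call without ODR replicate 2 (adjusted p from 0.0531 to 0.173) and without OB replicate 1 (adjusted p from 0.0997 to 0.272). Kdm2b, Cyp26a1 and Prl8a6 kept it without each library. Neural (ODR replicate 2), interferon (ODR replicate 1, OB replicate 2), BMP and p53 (ODR replicate 2, OB replicate 1) and endoderm (any library) lost their list call when the named library was left out.

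At day 6, genes of neural identity were higher in OB than in ODR. Fezf1, a forebrain transcription factor, rose from 1 ± 1.41 to 737 ± 131 (log2 fold change 8.72 ± 0.94, adjusted p = 1.58e-05, n = 4 OB and 2 ODR libraries). Pcsk1n, an inhibitor of a prohormone convertase, rose by 6.02 ± 0.47 (adjusted p = 1.45e-06) and Insm1, a zinc finger factor of neuroendocrine cells, by 4.13 ± 0.46 (adjusted p = 2.34e-05). Gldc, a subunit of the glycine cleavage system, went from 12 ± 2.83 to 229 ± 61.8. The neural list rose, with 9 of 18 members up and 0 down, 10 up adjusted over the list alone (median 1.30, adjusted p = 0.000148, and adjusted p = 0.054 with an estimated correlation). Its members Tubb3, a neuronal tubulin, Nkx6-1 and Pax6, transcription factors of the neural tube, reached 197 ± 52.9, 74.8 ± 28.7 and 14 ± 1.83 in OB against 11.5 ± 3.54, 12.5 ± 2.12 and 1 ± 1.41 in ODR.

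Pluripotency and epithelial genes also rose as lists in OB at day 6. Of 24 pluripotency genes 8 rose and 1 fell, 8 and 2 adjusted over the list alone (median 0.51, adjusted p = 0.00597, and adjusted p = 0.518 with an estimated correlation). Tfcp2l1, a transcription factor of naive stem cells, rose by 3.03 ± 0.41 (adjusted p = 0.000134). Eras, a Ras protein of embryonic stem cells, was 4.25 ± 0.957 in OB and listed at 0 in ODR. Of 22 epithelial genes 4 rose and 0 fell (median 0.79, adjusted p = 0.00325, and adjusted p = 0.644 with an estimated correlation). They include Grhl2, an epithelial transcription factor, at 22.2 ± 6.95 against 3 ± 1.41, and Spint1, a protease inhibitor of epithelia, at 22.5 ± 3.7 against 3 ± 4.24. The trophoblast list had 4 of 16 up and 0 down but did not pass its test (median 0.76, adjusted p = 0.0631). Tfap2a, a factor of ectoderm and neural crest in that list, rose by 2.49 ± 0.28 (adjusted p = 2.43e-05). Perp, a p53 target and desmosome protein, rose from 58 ± 22.6 to 221 ± 24.7.

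Hox and interferon genes were called lower as lists in OB at day 6. The Hox list had 0 of 37 up and 8 down, 9 down adjusted over the list alone (median -0.56, adjusted p = 0.000398, and adjusted p = 0.518 with an estimated correlation). Hoxd8 fell by 1.44 ± 0.21 (adjusted p = 0.000311), Hoxd3 by 2.93 ± 0.56 (adjusted p = 0.00264) and Hoxd13 by 2.14 ± 0.46 (adjusted p = 0.00616). Interferon response genes had 0 of 26 up and 13 down, 21 down adjusted over the list alone (median -1.20, adjusted p = 3.45e-11, and adjusted p = 0.379 with an estimated correlation). Rtp4 was 19.8 ± 5.32 against 114 ± 20.5, and Xaf1 and Ifit1 had log2 fold changes of -2.08 ± 0.40 and -2.69 ± 0.56. Other large decreases were those of Icam2, an adhesion molecule of endothelium and leukocytes (25.5 ± 7.19 against 281 ± 55.2), Gpr65, a proton-sensing receptor (24.2 ± 17.4 against 212 ± 27.6), and the peptide hormone gene Ucn3 (31 ± 9.93 against 409 ± 1.41). Acp5, the tartrate-resistant acid phosphatase of osteoclasts, was 44.8 ± 20.2 against 362 ± 62.9, and Phf19, a PRC2 accessory subunit, 10.2 ± 4.5 against 67.5 ± 0.707.

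Altogether 795 genes rose and 666 fell between OB and ODR at day 6, where Kdm2b was higher by at least 6.20 ± 0.24 and Kdm2a differed by 0.24 ± 0.81 (adjusted p = 0.913). ESC-high genes had 48 of 373 up and 11 down and MEF-high genes 51 of 781 up and 88 down, 57 and 15, and 56 and 104, adjusted over each set alone. Their adjusted p was 0.00193 upward and 0.0229 downward, and 0.182 and 0.370 with an estimated correlation. The count of 1461 dropped to 568 without ODR replicate 1 and 520 without ODR replicate 2. Of the 25 called genes of the text, 17 kept their call without each library. The others lost it without ODR replicate 1 (Grhl2, adjusted p = 0.0703, and Hoxd13, 0.0811), ODR replicate 2 (Spint1, 0.187, Pax6, 0.127, Perp, 0.0755, Xaf1, 0.0749, Ifit1, 0.107) or either (Ucn3, 0.0502 and 0.0534). The pluripotency list lost its call without ODR replicate 1 (0.0843) and the MEF-high set without ODR replicate 2 (0.280).

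**Figure D2:**
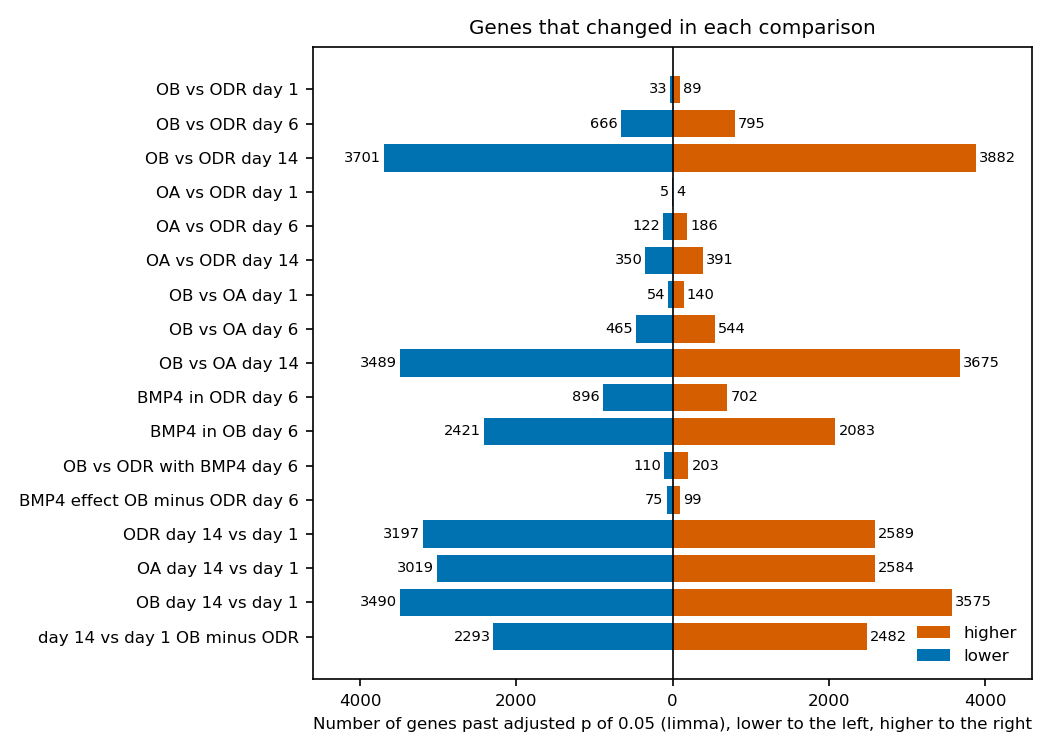
Number of genes with an adjusted p below 0.05 in each comparison, with bars to the right for genes higher and to the left for genes lower in the first-named group. OB against ODR goes from 122 genes at day 1 to 1461 at day 6 and 7583 at day 14, and OA against ODR from 9 to 308 and 741.

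By day 14, OB cells differed from ODR cells in 7583 genes, 54.7% of those tested, with 3882 higher and 3701 lower (n = 3 and 3). Several developmental regulators present in OB were listed at 0 in ODR: Lin28a, an RNA-binding protein of stem cells (677 ± 57.8), Nkx1-2 (467 ± 56.1), the caudal homeobox gene Cdx2 (187 ± 18.0), Hoxb1 (107 ± 11.4), the primitive streak factor T (51.3 ± 8.02) and the epithelial cadherin gene Cdh1 (37.3 ± 27.2). Igdcc3, an immunoglobulin superfamily gene, rose by 8.26 ± 0.73 (adjusted p = 7.34e-08) from 3 ± 1.73 in ODR. Col2a1, a collagen of cartilage and notochord, rose by 7.95 ± 0.72 (adjusted p = 9.27e-08) from 0.667 ± 1.15. Crabp2, a retinoic acid binding protein, rose by 7.43 ± 0.45 (adjusted p = 2.59e-09), and Sall4, a stem cell transcription factor, from 2.67 ± 1.53 to 323 ± 27.7. Kdm2b was 4.25 ± 0.23 higher (adjusted p = 1.1e-09). Kdm2a differed by -0.13 and Pou5f1 by -0.47 ± 0.23, without passing the test (adjusted p = 0.899 and 0.0924).

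Proliferation and glycolysis genes rose as lists in OB at day 14. All 30 cell cycle genes rose (median 1.95, adjusted p = 2.55e-16, and adjusted p = 0.474 with an estimated correlation), 30 also adjusted over the list alone. Among them, the mitotic kinase gene Cdk1 went from 262 ± 8.96 to 724 ± 22.4, the ribonucleotide reductase subunit Rrm2 from 249 ± 31.6 to 1224 ± 25, and the replicative helicase subunit Mcm7 rose by 2.48 ± 0.16 (adjusted p = 4.74e-09). Of 21 glycolysis genes 17 rose and 2 fell, the same adjusted over the list alone (median 1.71, adjusted p = 2.04e-06, and adjusted p = 0.474 with an estimated correlation). The glucose transporter Slc2a1 went from 352 ± 14.3 to 2841 ± 150 and the pyruvate kinase Pkm from 3972 ± 262 to the ceiling.

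Hox, epithelial and pluripotency genes were called higher as lists in OB at day 14. The Hox list had 26 of 37 up and 2 down, 29 and 2 adjusted over the list alone (median 1.57, adjusted p = 2.04e-06, and adjusted p = 0.474 with an estimated correlation). Hoxa9 rose by 3.32 ± 0.31 and Hoxd13 fell by 2.73 ± 0.44. Epithelial genes had 14 of 22 up and 0 down (median 2.09, adjusted p = 0.00141, and adjusted p = 0.614 with an estimated correlation), with the simple epithelial keratin Krt8 up by 4.15 ± 0.69. Pluripotency genes had 11 of 24 up and 3 down, 11 and 4 adjusted over the list alone (median 0.97, adjusted p = 0.0278, and adjusted p = 0.528 with an estimated correlation). ESC-high genes had 192 of 373 up and 43 down (193 and 44 adjusted over the set alone) and MEF-high genes 102 of 781 up and 383 down (109 and 387). Both calls held with an estimated correlation (adjusted p = 0.0255 and 0.0378). Polycomb genes moved in both directions: 5 of 10 PRC1.1 subunits rose and 1 fell (adjusted p = 0.138), and 13 of 26 other Polycomb subunits rose and 7 fell (adjusted p = 0.269). The PRC2 cofactor Jarid2 was at 944 ± 188 against 138 ± 13.1, the PRC2 methyltransferase Ezh2 at 826 ± 62.6 against 176 ± 12.5 and the PRC1.1 subunit Bcor at 624 ± 111 against 237 ± 31.

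Several other lists held members past the threshold at day 14 without passing their test. Trophoblast genes had 6 of 16 up and 2 down (adjusted p = 0.316), among them the imprinted gene Peg10, at 9508 ± 7983 with a library at the ceiling against 102 ± 14.2. BMP pathway targets had 10 of 29 up and 6 down (adjusted p = 0.632), and the BMP-induced inhibitors of differentiation Id1 and Id3 rose by 2.79 ± 0.55 and 2.70 ± 0.38. Endoderm had 4 up and 5 down of 19, mesoderm 3 up and 3 down of 16, neural 7 up and 2 down of 18 and chondrocyte 6 up and 1 down of 11. Keratinocyte genes had 2 up and 2 down of 11, endothelial 3 and 5 of 13 and muscle 1 and 2 of 10. Adipocyte genes had 2 and 2 of 7, germline 1 and 1 of 12, and immediate early and heat shock genes 1 and 5 of 20. The adjusted p of these 10 lists ran from 0.213 to 0.956.

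Fibroblast, p53 and interferon genes were called lower as lists in OB at day 14. Fibroblast and mesenchymal genes had 5 of 40 up and 18 down (median -0.66, adjusted p = 0.0163, and adjusted p = 0.614 with an estimated correlation). Lox, which crosslinks collagen, fell from 645 ± 97.4 to 143 ± 59.3 and Tgfb1 by 1.67 ± 0.15, whereas N-cadherin (Cdh2) rose from 566 ± 51.4 to 1605 ± 226. The p53 and Ink4 list had 1 of 22 up and 14 down, 15 down adjusted over the list alone (median -0.73, adjusted p = 0.00137, and adjusted p = 0.528 with an estimated correlation). Cdkn1a (p21) fell by 0.81 ± 0.12, Ccng1 by 1.39 ± 0.17 and the death receptor Fas by 2.42 ± 0.31. The 1 member that rose, the BH3-only gene Pmaip1, went from 9.67 ± 2.89 to 253 ± 13.6. Interferon genes had 0 of 26 up and 19 down, 21 down adjusted over the list alone (median -1.60, adjusted p = 2.08e-06, and adjusted p = 0.528 with an estimated correlation). The RNA sensor Ddx58 was 144 ± 15.4 against 532 ± 22.5, and Bst2 fell by 2.73 ± 0.32. Senescence-associated secretory genes had 3 of 20 up and 7 down (adjusted p = 0.215), and macrophage and leukocyte genes 1 of 15 up and 3 down (adjusted p = 0.232). The macrophage marker Cd68 was 4.67 ± 1.15 against 23 ± 3.61. Ucn3, Gpr65 and Acp5, lower already at day 6, fell by 6.37 ± 0.73, 5.24 ± 0.55 and 5.03 ± 0.50. The 38 called genes of the text for this day kept their call without each library.

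**Figure D3:**
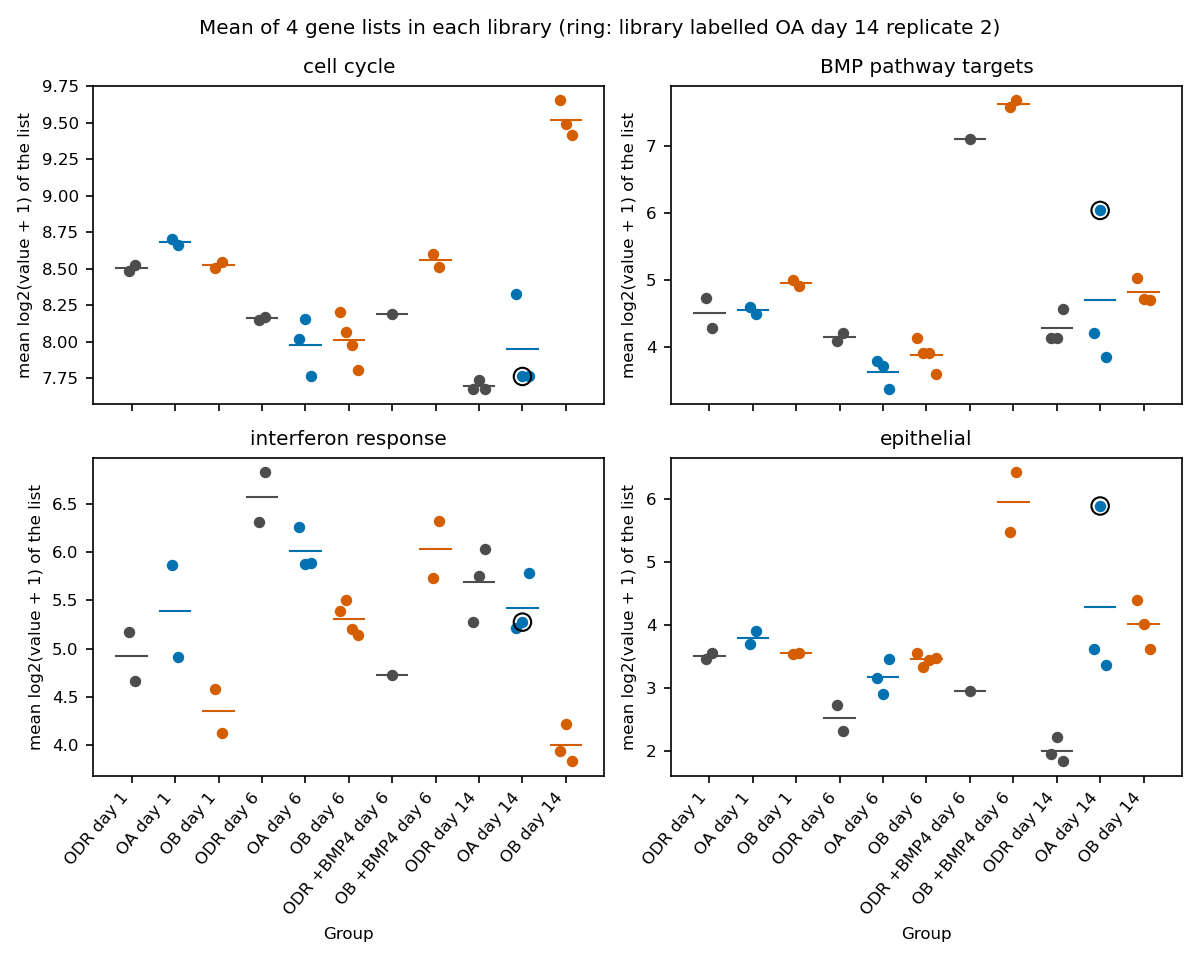
Mean log2(value + 1) of the cell cycle, BMP pathway, interferon and epithelial lists, 1 point per library with a short line at the mean of each group. The ring marks the library labelled OA day 14 replicate 2, with an epithelial list mean of 5.883 against 3.625 and 3.361 in the other OA libraries of that day.

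OA differed little from ODR at day 1 (4 genes up and 5 down, with 714 genes at an unadjusted p below 0.05, n = 2 and 2). The signalling gene Gng3, a G protein subunit of neurons, was 133 ± 32.5 against 6.5 ± 2.12 (adjusted p = 0.00878), and the integrin gene Itga3 fell by 1.19 ± 0.19 (adjusted p = 0.0095). Hoxd8 fell from 58.5 ± 2.12 to 14 ± 1.41 (adjusted p = 0.000723). Kdm2a was 13992 ± 6644 against 1034 ± 311, which did not pass the test (at least 3.70 ± 0.94, adjusted p = 0.237). With the library labelled OA day 14 replicate 2, whose Kdm2a value was 721, left out of the pooled spread, the same Kdm2a difference had an SE of 0.24 and passed (adjusted p = 3.72e-07). Camera called interferon (0 of 26 up and 0 down, median 0.45), cell cycle (0 and 0 of 30, median 0.20), germline (0 and 0 of 12, median 0.55) and ESC-high genes (0 and 0 of 373, 1 up adjusted over the set alone) upward. Their adjusted p was 0.000125, 0.000135, 0.0268 and 0.0153. It called Hox genes (0 of 37 up and 1 down, 2 down adjusted over the list alone) and other Polycomb subunits (0 and 0 of 26) downward, with adjusted p of 4.17e-06 and 0.0328. With an estimated correlation the adjusted p was 0.565, 0.704, 0.356, 0.331, 0.356 and 0.356. The count of 9 became 17 without ODR replicate 2 and 15 without OA replicate 2, and limma called 0 in a fit of only these groups (1158 at an unadjusted p below 0.05). Gng3 and Itga3 lost their call without ODR replicate 1 (adjusted p = 0.143 and 0.220) and without OA replicate 1 (0.125 and 0.137). The interferon list had a median of 0.0335 and an adjusted p of 0.916 without OA replicate 1.

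At day 6, OA cells differed from ODR cells in 308 genes, including Dpp6, Ncald and Hoxd8. Dpp6, a potassium channel auxiliary subunit, rose by 2.80 ± 0.37 (adjusted p = 0.000648, n = 3 OA and 2 ODR libraries) and Ncald, a neuronal calcium sensor, fell by 2.24 ± 0.33 (adjusted p = 0.0022). Hoxd8 fell by 1.98 ± 0.22 (adjusted p = 0.00024). Tubb3 was 131 ± 51.3 against 11.5 ± 3.54, Gng3 831 ± 184 against 101 ± 29.7, Krt8 47 ± 9 against 3.5 ± 2.12, and Icam2 40.7 ± 23.4 against 281 ± 55.2. Spint1 rose by 3.11 ± 0.69 (adjusted p = 0.0236) and Kdm2a by at least 4.57 ± 0.86 (adjusted p = 0.00859). Epithelial genes had 4 of 22 up and 0 down (median 0.18, adjusted p = 0.0207) and Hox genes 0 of 37 up and 3 down, 9 down adjusted over the list alone (median -0.55, adjusted p = 4.58e-08). Interferon genes had 0 of 26 up and 1 down (median -0.58, adjusted p = 0.000187). With an estimated correlation these adjusted p were 0.730, 0.267 and 0.559. Cell cycle genes had 0 and 0 of 30 called and a median of -0.21 (adjusted p = 0.0207), and immediate early genes 1 and 0 of 20 and a median of 0.17 (adjusted p = 0.0211). With an estimated correlation, their adjusted p was 0.730 and 0.267.

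The day 6 difference between OA and ODR, 186 genes up and 122 down, depended on single libraries. The count of 308 was 124 without ODR replicate 1, 28 without ODR replicate 2, 128 without OA replicate 1, 189 without OA replicate 2, 163 without OA replicate 3 and 48 in a fit of only these groups. Dpp6, Ncald and Hoxd8 kept their call without each library. Kdm2a, Gng3 and Icam2 lost it without ODR replicate 1 (adjusted p = 0.0655, 0.110 and 0.0603) or ODR replicate 2 (0.107, 0.0894 and 0.0546). The Kdm2a fold itself stayed at 4.58 and 4.56, and its adjusted p was 2.96e-09 with the library labelled OA day 14 replicate 2 left out of the pooled spread. Tubb3 lost it without these or OA replicate 1 (0.124, 0.107 and 0.0633) and Krt8 without these or OA replicate 3 (0.196, 0.107, 0.0802 and 0.0635). Spint1 lost it without ODR replicate 2 or any OA library (0.454, 0.0590, 0.0561 and 0.0767). The epithelial call was lost without ODR replicate 2 (0.0811) or OA replicate 3 (0.121), and the interferon call without ODR replicate 2 (0.0740).

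By day 14, epithelial genes stood out in OA. Their list had 10 of 22 members up and 0 down, 15 up adjusted over the list alone (median 1.97, adjusted p = 3.03e-15, and adjusted p = 0.273 with an estimated correlation, n = 3 and 3). The keratins Krt8 and Krt18 rose by 5.17 ± 0.69 (adjusted p = 0.000389) and 3.74 ± 0.56 (adjusted p = 0.000941) and the desmosomal plakophilin Pkp3 by 3.59 ± 0.50 (adjusted p = 0.000509). The tight junction gene Cldn4 was 157 ± 254 in OA and listed at 0 in ODR. Epha1, an ephrin receptor, rose by 4.19 ± 0.69 (adjusted p = 0.00191). The library labelled OA day 14 replicate 2, whose Kdm2a value of 721 lies with the libraries outside OA, had an epithelial list mean of 5.883 against 3.625 and 3.361 in replicates 1 and 3. Without it the epithelial median was 1.21 (adjusted p = 2.17e-08). Krt8 then rose by 4.15 ± 0.55, Krt18 by 2.99 ± 0.50, Pkp3 by 3.20 ± 0.53 and Epha1 by 2.91 ± 0.37. Cldn4, listed at 0 in ODR, then had a log2 fold change of 3.44 ± 0.66, whose size rests on the 1 added before the log.

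The pluripotency list and the ESC-high set were called higher in OA at day 14. Pluripotency genes had 8 of 24 up and 0 down, 9 up adjusted over the list alone (median 0.57, adjusted p = 0.000506, and adjusted p = 0.273 with an estimated correlation). Tfcp2l1 was 447 ± 96.7 against 109 ± 4.93, the TGF-beta family ligand Gdf3 42.7 ± 28.7 against 2.67 ± 0.577, and Lin28a 27 ± 36.4 against a listing at 0. L1td1, a stem cell RNA-binding protein, rose by 3.43 ± 0.37 (adjusted p = 8.34e-05). ESC-high genes had 42 of 373 up and 9 down, 60 and 15 adjusted over the set alone (median 0.33, adjusted p = 1.46e-05, and adjusted p = 0.0529 with an estimated correlation). MEF-high genes had 26 of 781 up and 50 down (median -0.10, adjusted p = 0.0249, and adjusted p = 0.376 with an estimated correlation). Their median was 0.0439 and their adjusted p 0.339 without the library labelled OA day 14 replicate 2. Trophoblast genes had 4 of 16 up and 1 down (median 1.13, adjusted p = 0.000585, and adjusted p = 0.273 with an estimated correlation), with Peg10 at 781 ± 480 against 102 ± 14.2. Cell cycle genes had 2 of 30 up and 0 down (median 0.26, adjusted p = 0.000218, and adjusted p = 0.710 with an estimated correlation). Glycolysis genes had 3 of 21 up and 0 down (median 0.36, adjusted p = 0.000585, and adjusted p = 0.609 with an estimated correlation). Of these, Rrm2 rose by 0.74 ± 0.14, and the enzymes of glycolysis Pfkp and Aldoc by 1.36 ± 0.22 and 2.01 ± 0.35. Without the library labelled OA day 14 replicate 2, the trophoblast median was 0.25 (adjusted p = 0.0396), the ESC-high median 0.21 (0.00107), the pluripotency median 0.63 (0.00219) and the cell cycle median 0.37 (4.13e-07). The cell cycle call was lost without OA replicate 1 (adjusted p = 0.542) and the glycolysis call without the library labelled OA day 14 replicate 2 (0.240).

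Other genes of OA at day 14 included the cardiac protease Corin (146 ± 31.5 against 15.7 ± 6.43) and the myosin heavy chain Myh2 (1274 ± 1924 against 17.3 ± 9.71). The neuronal Stmn2 rose by 1.76 ± 0.29 and the cartilage collagen Col9a1 by 2.44 ± 0.53, while the chondrocyte factor Sox6 fell by 1.83 ± 0.36. B3galt5, a galactosyltransferase, fell from 121 ± 22.3 to 9 ± 6.08, the chemokine Cxcl12 from 1158 ± 42 to 310 ± 253, Ucn3 by 3.53 ± 0.73 and Itgb2l by 3.50 ± 0.71. In total 391 genes rose and 350 fell, while a fit of only these groups called 1 gene. The count of 741 was 417 without ODR replicate 1, 344 without ODR replicate 2, 1228 without OA replicate 3 and 772 without the library labelled OA day 14 replicate 2. Of those 772, 450 were among the 741, and no gene of the 741 was called in the opposite direction. Kdm2a was 12700 ± 10374 against 1011 ± 138 (at least 2.65 ± 0.77, adjusted p = 0.0513), and at least 4.22 ± 0.22 higher without that library (adjusted p = 1.08e-08). Other folds also moved without it: Myh2 rose by 3.29 ± 0.50 in place of 4.76 ± 0.82, Col9a1 rose by 1.81 ± 0.50, and Cxcl12 fell by 1.39 ± 0.21 in place of 2.60 ± 0.60. Itgb2l fell by 2.655 ± 0.67 and B3galt5 by 3.16 ± 0.39, and Gdf3 rose by 4.04 ± 0.65. Cxcl12 lost its call without ODR replicate 2 (adjusted p = 0.0554).

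Compared directly with OA, OB was higher for Kdm2b (6.14 ± 0.28 at day 1, 6.38 ± 0.21 at day 6 and 4.28 ± 0.23 at day 14, the first 2 lower bounds). Kdm2a was lower in OB (-3.69 ± 0.94, -4.33 ± 0.72 and -2.79 ± 0.77, with adjusted p of 0.0611, 0.00114 and 0.00536). Each is a lower bound in size, because OA held values at the ceiling. Without the library labelled OA day 14 replicate 2, the day 14 Kdm2a value was -4.35 ± 0.22 (adjusted p = 2.17e-09), also a lower bound in size. The day 1 value, unchanged in size, then had an SE of 0.24 and passed (adjusted p = 9.83e-08). At day 1, 140 genes were higher and 54 lower in OB (n = 2 and 2). Cyp26a1 was higher by 6.56 ± 0.55 and the proteoglycan Spock1 was 236 ± 90.5 against 19.5 ± 3.54. Prl8a6 fell by 1.29 ± 0.08, and the RNA sensor Tlr3 was 43.5 ± 9.19 against 122 ± 10.6. Interferon genes had 0 of 26 up and 1 down, 13 down adjusted over the list alone (median -1.20, adjusted p = 1.09e-11, and adjusted p = 0.525 with an estimated correlation). The interferon median was -0.47 without OA replicate 1 and -1.77 without OA replicate 2. At day 6, 544 were higher and 465 lower (n = 4 and 3). Gldc (229 ± 61.8 against 11.7 ± 2.89), Sall4 (43 ± 15.8 against 2.67 ± 2.89) and Pcsk1n (3.17 ± 0.42) were higher. The kidney injury marker Havcr1 (21 ± 5.29 against 179 ± 39.3), the endocytic receptor Cubn (256 ± 40.1 against 1291 ± 203) and the calcium-binding S100a4 (-1.76 ± 0.26) were lower. The count of 194 at day 1 was 110 without OA replicate 1, 52 without OA replicate 2 and 33 without OB replicate 1, and 2 in a fit of only these groups. The count of 1009 at day 6 was 542, 558, 655 and 631 without OA replicate 2, OA replicate 3, OB replicate 1 and OB replicate 3.

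At day 14 OB and OA differed in 7164 genes, 3675 higher and 3489 lower in OB (n = 3 and 3), and in 7199 without the library labelled OA day 14 replicate 2. Cell cycle genes had 30 of 30 up (median 1.70), Hox genes 30 of 37 up and 1 down (31 and 1 adjusted over the list alone, median 1.56), glycolysis 17 of 21 up and 2 down (median 1.19), and interferon 0 of 26 up and 19 down (20 down adjusted over the list alone, median -1.40). Their adjusted p was 6.35e-16, 7.57e-08, 1.4e-05 and 1.03e-05, and adjusted p = 0.416, 0.416, 0.501 and 0.501 with an estimated correlation. The stem cell factor Sox2 was 289 ± 14.2 against 7 ± 10.4 and the somite factor Meox1 122 ± 47.2 against 1.67 ± 2.08. The planar polarity cadherin Celsr1 rose by 5.26 ± 0.69 (adjusted p = 6.8e-06). Slc2a1 rose by 2.44 ± 0.13 and Ezh2 by 1.93 ± 0.16. The hyaluronan receptor Cd44 (249 ± 47.3 against 1025 ± 375), the tachykinin precursor Tac1 (63.7 ± 19.3 against 850 ± 513), Myo1d (-3.29 ± 0.22) and Layn (-3.42 ± 0.31) were lower. The called genes of the text in these direct comparisons kept their call without each library.

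In ODR cells at day 6, BMP pathway genes were higher in the 1 library with BMP4 that carries no second label than in the 2 without. Smad6, an inhibitor of BMP signalling, was 662 and the osteogenic factor Sp7 was 10 with BMP4, both listed at 0 without it. Id3 went from 21 ± 1.41 to 780 (log2 fold change 5.15 ± 0.57, adjusted p = 3.37e-05) and the Notch and BMP target Hey1 from 36 ± 18.4 to 724. BMP pathway targets had 19 of 29 up and 1 down, 21 and 2 adjusted over the list alone (median 3.46, adjusted p = 1.25e-11, and adjusted p = 0.339 with an estimated correlation). The member that fell was the matricellular gene Smoc2 (-3.12 ± 0.61). Other genes rose as well: the BMP and Wnt antagonist Sost (383) was listed at 0 without BMP4, and the proteoglycan Fmod was 542 against 0.5. The tenascin Tnn was 4217 against 12 ± 5.66, the cartilage factor Sox9 420 against 15.5, and osteopontin (Spp1) 6251 against 818.5 ± 44.5. Foxq1 (364) and the neural crest factor Pax3 (12) were also listed at 0 without BMP4. Fabp7, a fatty acid binding protein of radial glia, rose by 3.72 ± 0.69 and Stmn2 went from 374 ± 5.66 to 1476.

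Interferon genes were called lower as a list in ODR with BMP4. The list had 0 of 26 up and 13 down, 19 down adjusted over the list alone (median -1.75, adjusted p = 1.04e-11, and adjusted p = 0.339 with an estimated correlation). Oasl2 went from 160 ± 92.6 to 8 (adjusted p = 0.00141), Ddx58 from 756 ± 41.7 to 250 (adjusted p = 0.00196), and Mx1 fell by 2.92 ± 0.51 (adjusted p = 0.00145). Hox genes had 3 of 37 up and 0 down, none adjusted over the list alone (median 0.42, adjusted p = 0.00205, and adjusted p = 0.673 with an estimated correlation). Among mesenchymal genes 6 of 40 rose and 5 fell (adjusted p = 0.283), with the TGF-beta receptor Tgfbr2 at 438 against 1248 ± 164. The collagen Col5a2 fell by 0.93 ± 0.21. Neuronal pentraxin Nptx2 went from 874 ± 119 to 21, Igfbp5 from 3935.5 ± 1607 to 738, the matrix protein gene Thbs4 from 166 ± 68.6 to 1, and Sox6 fell by 3.89 ± 0.54. Kdm2b, Kdm2a and Pou5f1 did not pass the test (log2 fold changes of -0.07, -0.20 and 0.00). In all, 702 genes rose and 896 fell. This count of 1598 became 985 without ODR replicate 1 and 770 without ODR replicate 2, where Thbs4 lost its call (adjusted p = 0.0842). With the spread of only these groups limma called 0 genes, beside 3060 at an unadjusted p below 0.05. The library under both day 6 labels had Id3 at 28 and Smad6 at 0. Its BMP pathway list mean was 3.956, against 4.079 and 4.211 in ODR without BMP4 and 7.1 in the other library with BMP4. Its Pearson r was 0.970 with ODR replicate 1 without BMP4 and 0.898 with that other library. These values go against its BMP4 label. With it in both groups, and so also among the libraries with BMP4, limma called 0 genes, and 1194 had an unadjusted p below 0.05. With it in ODR without BMP4 only, the count stayed within 1.5 times.

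In OB cells, BMP4 changed 4504 genes, 2083 up and 2421 down (n = 2 with and 4 without BMP4). BMP pathway targets had 22 of 29 up and 1 down, the same adjusted over the list alone (median 3.88, adjusted p = 6.08e-14, and adjusted p = 0.159 with an estimated correlation). The BMP antagonist Nog rose by 8.21 ± 1.00 (adjusted p = 1.31e-05), Smad6 by 7.83 ± 0.98 (adjusted p = 1.54e-05) and Smad7 by 3.85 ± 0.35 (adjusted p = 8.41e-07). Sp7 rose by 5.33 ± 0.31 (adjusted p = 6.68e-09) and Id3 by 4.24 ± 0.40 (adjusted p = 1.15e-06). The homeobox gene Tlx2 went from 0.25 ± 0.5 to 680 ± 139. Hand1, a factor of trophoblast and heart (596 ± 103), was listed at 0 without BMP4. Trophoblast genes had 10 of 16 up and 0 down (median 3.51, adjusted p = 2.03e-05, and adjusted p = 0.159 with an estimated correlation). Gata3 was 265 ± 46.7 against 27.8 ± 3.4, and secretin (Sct) was 242 ± 189 and listed at 0 without BMP4. Epithelial genes had 15 of 22 up and 1 down, 16 and 1 adjusted over the list alone (median 2.27, adjusted p = 2.02e-06, and adjusted p = 0.443 with an estimated correlation). The tight junction gene Cldn4 went from 2.75 ± 1.5 to 902 ± 347, and Cldn3 was 69 ± 19.8 and listed at 0 without BMP4. The epithelial factor Ovol2 rose by 4.75 ± 0.59, and Grhl2 fell from 22.2 ± 6.95 to 4 ± 1.41.

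Endoderm, mesoderm and pluripotency genes moved in both directions in OB with BMP4. Endoderm had 8 of 19 up and 5 down (adjusted p = 0.224). Sox17 was 132 ± 11.3 against 0.5, and the laminin Lama1 rose by 4.54 ± 0.62 and Gata6 by 2.09 ± 0.34. Mesoderm had 8 of 16 up and 4 down (adjusted p = 0.0627), with Wnt3 at 266 ± 14.1 against 2. Pluripotency had 7 of 24 up and 2 down (adjusted p = 0.233), with Tbx3 at 775 ± 228 against 32.8 ± 3.86. Klf4 rose by 2.51 ± 0.33. The cell cycle list was called higher, with 15 of 30 up and 0 down, 18 up adjusted over the list alone (median 0.55, adjusted p = 1.58e-06, and adjusted p = 0.490 with an estimated correlation). Among them were Rrm2 (1414 ± 28.3 against 424 ± 61.9) and Cdk1 (0.63 ± 0.09). Hox genes had 12 of 37 up and 1 down (median 0.73, adjusted p = 0.00219, and adjusted p = 0.496 with an estimated correlation), and Hoxa3 rose by 2.39 ± 0.38. Other Polycomb subunits had 7 of 26 up and 2 down, 11 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.00718, and adjusted p = 0.293 with an estimated correlation), and Phf19 rose by 2.99 ± 0.42.

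The p53 list was called lower in OB with BMP4, with 0 of 22 up and 8 down, 9 down adjusted over the list alone (median -0.33, adjusted p = 0.00663, and adjusted p = 0.490 with an estimated correlation). They include Ccng1 (-0.93 ± 0.18) and the kinase Plk2 (-1.44 ± 0.30). The interferon list was called higher, with 9 of 26 up and 0 down (median 0.78, adjusted p = 0.0046, and adjusted p = 0.605 with an estimated correlation). Rtp4 was 78 ± 17 against 19.8 ± 5.32, and the ubiquitin-like Isg15 rose by 1.85 ± 0.51. Large decreases were found for Thbs4 (2 ± 2.83 against 878 ± 188), Pde1a (42.5 ± 7.78 against 1853 ± 286), Egflam (-5.94 ± 0.87), A2m (-5.79 ± 1.01), nestin (Nes, -1.86 ± 0.28) and the mesenchymal factor Twist1 (168 ± 7.78 against 475 ± 75.3). Kdm2b, Kdm2a and Pou5f1 did not pass the test, with -0.50 ± 0.24 and an adjusted p of 0.12 for Kdm2b, which had values at the ceiling in both groups. The count of 4504 was 2514 without OB with BMP4 replicate 2, where Isg15 (adjusted p = 0.203) and the interferon list (0.145) lost their call. The p53 list lost its call without OB with BMP4 replicate 1 (adjusted p = 0.134).

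**Figure D4:**
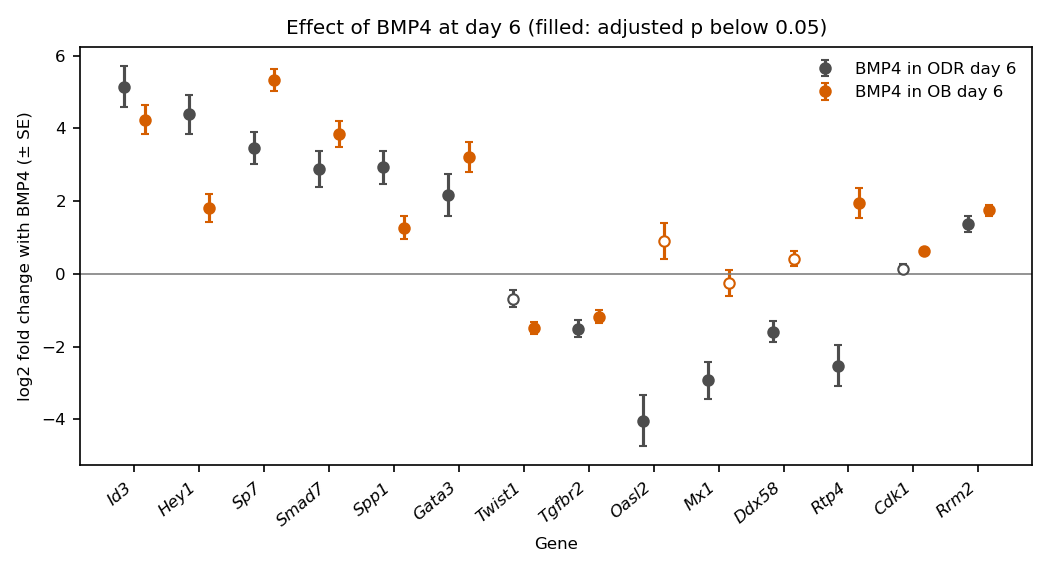
Log2 fold change with against without BMP4 at day 6 in ODR (1 and 2 libraries) and OB (2 and 4 libraries) for named genes, with bars for the SE and filled points where the adjusted p is below 0.05. Id3 is 5.15 in ODR and 4.24 in OB, whereas Oasl2 is -4.04 in ODR.

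The test of the difference between the BMP4 effects in OB and ODR called 99 genes with a higher and 75 with a lower effect in OB. The interferon list differed most in number, with 10 of 26 higher and 0 lower, 21 higher adjusted over the list alone (median 2.50, adjusted p = 3.28e-28). This call held with an estimated correlation (adjusted p = 0.0397). Oasl2 (4.94 ± 0.86), Rtp4 (4.47 ± 0.71) and Ddx58 (2.01 ± 0.35) were among its members. The desmosomal cadherin Dsg2 (6.58 ± 0.85) and Phf19 (4.23 ± 0.73) were higher and the disintegrin gene Adam23 (-3.05 ± 0.40) lower in effect. With BMP4 in both, OB exceeded ODR in 203 genes and was lower in 110 (n = 2 and 1), with Kdm2b higher by at least 5.77 ± 0.34. Trophoblast genes had 6 of 16 higher and 0 lower, 9 higher adjusted over the list alone, and ESC-high genes 19 of 373 higher and 0 lower, 36 and 2 adjusted over the set alone. Both calls held with an estimated correlation (adjusted p = 0.023 and 0.0117). Epithelial genes had 8 of 22 higher and 0 lower, 15 higher adjusted over the list alone (adjusted p = 2.49e-16, and adjusted p = 0.0863 with an estimated correlation). Peg10 (11884 ± 9626 against 97), Dsg2 (135 ± 69.3 against 1), Tfap2a (2.17 ± 0.40), Krt8 (270 ± 190 against 4) and Ovol2 (31 ± 1.41, listed at 0 in ODR) were higher. Epha3 (240 ± 27.6 against 1080), Pcdh18 (-2.34 ± 0.34) and the limb factor Shox2 (-1.95 ± 0.31) were lower. Without OB with BMP4 replicate 2 the counts of 174 and 313 were 46 and 57. Oasl2 then lost its call in both (adjusted p = 0.0525 and 0.271), Ddx58 in the former (0.0525) and Krt8 in the latter (0.102). For the 313 limma called 0 in a fit of only these groups (2114 at an unadjusted p below 0.05). The count of 174 was also 112, 68, 115 and 115 without ODR replicate 1, ODR replicate 2, OB replicate 2 and OB replicate 3.

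From day 1 to day 14, ODR and OA cells lost proliferation genes while OB cells gained them. Cell cycle genes had 0 of 30 up and 23 down in ODR (median -0.83), 0 up and 20 down in OA (21 down adjusted over the list alone, median -0.78) and 25 up and 0 down in OB (median 1.02). Their adjusted p was 1.79e-06, 4.59e-06 and 4.03e-08, and 0.841, 0.586 and 0.345 with an estimated correlation. The test of the difference between OB and ODR had 28 of 30 higher and 0 lower (median 1.998, adjusted p = 3.96e-18, and adjusted p = 0.304 with an estimated correlation). Cdk1 went from 550 ± 35.4 to 262 ± 8.96 in ODR and fell by 0.88 ± 0.09 in OA, and Rrm2 fell by 1.86 ± 0.16 and 1.40 ± 0.16. Pcna and Mcm7 rose by 1.35 ± 0.12 and 1.65 ± 0.18 in OB (n = 3 and 2). Glycolysis genes had 17 of 21 up and 1 down in OB (median 1.16, adjusted p = 4.18e-07, and adjusted p = 0.26 with an estimated correlation). Slc2a1 rose by 2.65 ± 0.15, and the kinase Pdk1 was 741 ± 219 against 15 ± 8.49. Pdk1 also rose by 2.56 ± 0.35 in ODR and 2.57 ± 0.35 in OA.

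Macrophage and leukocyte genes fell in all 3 combinations over this time, with 1 of 15 up and 12 down in each. The medians were -3.10, -2.84 and -3.23 in ODR, OA and OB (adjusted p = 0.000336, 0.000464 and 5.95e-05, and adjusted p = 0.401, 0.444 and 0.157 with an estimated correlation). Among signalling adaptors, Tyrobp fell from 16.5 ± 0.707 to 0.333 ± 0.577 and Fcer1g by 3.69 ± 0.45 in ODR. Fcer1g fell by 3.66 ± 0.45 in OA, and in OB it went from 15 ± 1.41 to a listing at 0. The mesenchymal list was called lower in OB (3 of 40 up and 20 down, median -0.76, adjusted p = 0.00194, and adjusted p = 0.509 with an estimated correlation), and Lox fell by 4.86 ± 0.24. Lox also fell by 2.65 ± 0.24 in ODR and 3.21 ± 0.24 in OA. In ODR, the contractile gene Tagln went from 3349 ± 482 to 55.7 ± 24.5 and S100a4 fell by 4.59 ± 0.31. Nt5e, which encodes the surface enzyme CD73, rose from 17 ± 1.41 to 15561 ± 5420, Igfbp5 by 3.65 ± 0.29, Sox1 by 7.49 ± 0.70 and Oasl2 by 2.82 ± 0.52. In OA, Nt5e and Sox1 rose by 8.39 ± 0.36 and 7.33 ± 0.70, and Tfcp2l1 by 6.12 ± 0.43. In OB, Igdcc3 (1139 ± 233) and Sall4 (323 ± 27.7) were listed at 0 at day 1, and Kdm2b fell by at least 1.91 ± 0.25.

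Genes of the p53 and Ink4 list fell in OB, 1 of 22 up and 19 down, 20 down adjusted over the list alone (median -1.20, adjusted p = 6.89e-08, and adjusted p = 0.157 with an estimated correlation). The cell cycle inhibitor Cdkn2b was 64.7 ± 18.2 against 476 ± 25.5, and Mdm2 fell by 1.58 ± 0.11. These falls were not particular to OB. Cdkn2b also fell by 2.33 ± 0.22 in ODR and 1.86 ± 0.22 in OA, and Mdm2 by 0.99 ± 0.11 and 0.76 ± 0.11. Hox genes had 26 of 37 up and 1 down in OB (median 1.28, adjusted p = 3.53e-06, and adjusted p = 0.26 with an estimated correlation). ESC-high genes had 186 of 373 up and 36 down and MEF-high genes 108 of 781 up and 390 down. These calls held with an estimated correlation (adjusted p = 0.0138 and 0.0222). The interferon list was called higher in ODR, with 12 of 26 up and 0 down (median 0.69, adjusted p = 0.0158, and adjusted p = 0.898 with an estimated correlation). This call was lost without ODR day 1 replicate 2 (adjusted p = 0.108) or ODR day 14 replicate 3 (0.0774). Of the 2 measured 2-cell-like genes, 1 fell in ODR and 2 fell in OA. Changes from day 1 to day 14 covered 2589 genes up and 3197 down in ODR, 2584 and 3019 in OA, and 3575 and 3490 in OB. The change differed between OB and ODR in 4775 genes, 2482 higher and 2293 lower in OB. Among these were Slc2a1 (3.12 ± 0.21), Pkm (2.24 ± 0.19), Cdk1 (1.57 ± 0.13), Jarid2 (2.73 ± 0.30), the lipid transporter Spns2 (-6.57 ± 0.96), Fas (-2.85 ± 0.50) and Bst2 (-2.78 ± 0.51). The genes of the text in the comparisons over time kept their call without each library. This statement does not cover the ODR and OA changes of Cdkn2b, Mdm2, Pdk1 and Lox.

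At day 9, 1 library of ODB and 1 of ODDR without BMP4 could be set side by side, with no test. Kdm2b was 18690 in ODB and 452 in ODDR, and 587 genes were higher and 676 lower in ODB by a log2 difference of at least 1. Pluripotency genes had a median difference of 1.28, with 14 of 24 higher and 6 lower by at least 1. Cell cycle genes had a median of 1.30, with 22 of 30 higher and 0 lower. Each median was above all 10000 matched random lists (percentile 100). Epithelial genes had a median of 1.03, with 12 of 22 higher and 2 lower (percentile 99.99). Fibroblast and mesenchymal genes were lower (median -0.95, percentile 0), as were p53 targets (-0.56, percentile 0). Nkx1-2 (372), Igdcc3 (276), the homeobox gene Cdx1 (202) and the lipoxygenase Alox15 (179) were listed at 0 in ODDR. Peg10 was 3320 against 138 and Epcam 108 against 7. The epidermal Sprr2f (-5.40), the mesothelial Msln (-5.20), Trnp1 (-4.56), Cpa4 (-4.25) and the Wnt enhancer Rspo1 (-4.09) were lower in ODB.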

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

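Of the tests in this part, those on the library labelled OA day 14 replicate 2 and those on scaling, normalization, GC content and transcript length were chosen only after the result was seen, and the others were written before.

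In the library labelled OA day 14 replicate 2, the BMP pathway list mean was 6.035 against 4.206 and 3.846 in OA day 14 replicates 1 and 3, with Id1 at 722, Id3 at 573 and Smad6 at 122. The library resembled the day 9 library under both BMP4 labels (Pearson r across genes 0.961) more than any library of its group (highest r 0.893). A mixture with RNA of an OA library is argued against by its Kdm2a value of 721, below the highest value outside OA of 1254 and the lowest other OA value of 9294. Loss of Kdm2a alone in an OA culture is argued against, if such a culture resembles ODR at day 14. The library's highest r with an ODR day 14 library was 0.889, below that 0.961. A wrong label stays open as a candidate explanation. Across genes, the library's difference from the other OA day 14 libraries followed the BMP4 response in OB with r = 0.636 (0.537 for the response in ODR). This r alone does not separate a wrong label from other causes. No biological explanation beyond the loss of Kdm2a was tested.

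The broad change in OB at day 14 covered 7583 genes against ODR. GC content and transcript length are argued against as its whole cause: their correction moved 394 of 13860 fold changes by more than their SE, and 96.3% of the calls were kept with the same sign. A scaling factor moves every gene of a library alike. The calls went both ways, 3882 higher and 3701 lower, of which 1839 and 1931 had a log2 fold change of at least 1 in size. A common factor cannot move genes in opposite directions, so large changes both ways argue against it as the whole cause. The even split and the median log2 fold change of 0.00865 over all genes add nothing. Columns that share nearly the same distribution set both beforehand. No common log2 shift of the OB libraries, from -2 to 2, left fewer than 7583 calls. That shift test decides nothing, because columns that share nearly the same distribution put the lowest count near a shift of 0 beforehand. What the submitters' normalization did stays open: median-of-ratios rescaling kept 98.8% of the calls, but it moved 0 fold changes by more than their SE (median move 0.0233), since the columns already share nearly the same distribution. A biological difference that comes with the OB combination may underlie the change and also stays open.

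With BMP4 the mean of the interferon list differed by -1.85 in ODR and by 0.72 in OB, the latter below the spread of up to 0.964 between libraries of a group (OA day 1) and with a list call lost without OB with BMP4 replicate 2 (adjusted p = 0.145) and with an estimated correlation (0.605). Macrophage and leukocyte RNA is argued against as the source of the fall in ODR, since that list had a median of 0.77 there (quartiles -0.24 and 1.28). For the fall in ODR, that spread of 0.964 lies between the bounds set in advance and stays open. A peculiarity of the lone ODR library with BMP4 also stays open: at day 9 the library under both BMP4 labels lay 1.35 lower than the ODDR library without BMP4 (a difference of -1.35), past the bound of 1 set in advance against it, but by less than that spread and in single libraries. A difference between the factor combinations in their response stays among the open explanations.

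With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 7583 genes for OB against ODR at day 14, where the highest other split called 2. It called 741 for OA against ODR, where the highest other called 95, and 7164 for OB against OA, where the highest other called 520. In each case 1 of the 10 splits, the real one, gave as many genes. For OB against OA at day 6, 1 of 35 splits gave as many as the real count of 1009, with 91 in the highest other. This is the smallest share that 35 splits can give. As the replicates may be technical, it does not exclude a chance difference between single cultures.

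The BMP4 effect at day 6 differed between OB and ODR in 174 genes by the test of the difference. The median log2 difference was 2.50 for the interferon list, 1.76 for epithelial, 2.40 for trophoblast, 0.53 for cell cycle and 0.64 for BMP pathway targets. It was 0.22 for other Polycomb subunits, 0.89 for endothelial, -0.57 for neural and 0.17 for ESC-high genes. With an estimated correlation the interferon call held (adjusted p = 0.0397), and the adjusted p was 0.267, 0.146, 0.267, 0.619, 0.232, 0.146, 0.267 and 0.411 for the others. The neural, BMP, endothelial and ESC-high calls were each lost without at least 3 single libraries. Among genes the differences were 4.47 for Rtp4, 4.94 for Oasl2, 2.01 for Ddx58, 6.58 for Dsg2, 4.23 for Phf19 and -3.05 for Adam23. Without OB with BMP4 replicate 2 the count was 46 and the calls of Oasl2 and Ddx58 were lost.

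The change from day 1 to day 14 differed between OB and ODR in 4775 genes by the test of the difference. The median log2 difference was 1.998 for cell cycle, 1.83 for glycolysis, 1.504 for Hox genes and 2.025 for epithelial genes. It was -0.83 for p53 targets, -1.13 for interferon, -0.44 for fibroblast and mesenchymal, 0.91 for ESC-high and -0.61 for MEF-high genes. The calls of the ESC-high and MEF-high sets held with an estimated correlation (adjusted p = 0.0413 for each), and the others had an adjusted p of 0.304, 0.304, 0.304, 0.531, 0.304, 0.531 and 0.531. The fibroblast call was lost without ODR day 1 replicate 2 (adjusted p = 0.0579). Among genes the differences were -1.38 for Kdm2b, 3.12 for Slc2a1, 2.24 for Pkm, 1.57 for Cdk1, 2.18 for Rrm2, 2.73 for Jarid2 and 1.89 for Ezh2. They were -6.57 for Spns2, -2.85 for Fas and -2.78 for Bst2.

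In the 4 OB day 6 libraries, Dixon's ratio for 1 library apart from the other 3 was past its 95% critical value for 6 genes. Chance alone gives about 1 in 20, which is 4.25 of the 85 genes and lists tested. Tfap2a was 306 in replicate 1 against 228 to 238 (ratio 0.872), Spint1 17 in replicate 2 against 24 to 25 (0.875) and Hoxa3 20 in replicate 2 against 10 to 11 (0.9). Tlx2, Sp7 and Ovol2 had a value of 1 in replicates 1, 2 and 4 and 0 in the others. Their ratio of 1 follows from the other 3 values being 0, so it says nothing about these libraries.

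Outside the tests, the day 9 library deposited under both labels with BMP4 had a BMP pathway list mean of 6.54, against 4.397 in ODDR and 4.352 in ODB without BMP4.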

How the results depend on the processing

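The placements of the shared day 6 library, the removal of the library labelled OA day 14 replicate 2 from the fit and the GC and length correction are tests chosen after seeing the data, and the other alternatives were planned. Quantile normalization, median-of-ratios rescaling, limma's trend and robust options and the GC and length correction left all 17 counts within 1.5 times. Over all alternatives, 264 counts stayed within 1.5 times and 79 moved. For the named genes 19108 values kept their direction and side of the threshold, 1630 lost the call and 19 gained it. For the gene lists, 2229 stayed the same, 315 lost the call and 2 reversed. The interferon list of OA against ODR at day 1 had medians from 0.0335 without OA replicate 1, where the direction of its test turned (adjusted p = 0.916), to 1.04 without OA replicate 2. The MEF-high median of OA against ODR at day 14 ran from -0.171 without OA replicate 1 to 0.0439 without the library labelled OA day 14 replicate 2. The cause of each was not tested. Depth is unknown and sets no stated limit, and the ceiling of 18690 limits folds of the factors.

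A log2 fold change of at least 1 beside the adjusted p left, by construction, fewer genes: 748 for OB against ODR at day 6 and 3770 at day 14, 186 and 410 for OA against ODR, and 488 and 3248 for OB against OA. It left 2257 for BMP4 in OB, 2913, 2779 and 3703 for ODR, OA and OB from day 1 to day 14, and 2999 for their difference between OB and ODR. A minimum of 100, with fewer genes tested, gave 80 for OB against ODR and 2 for OA against ODR at day 1. For the latter, a pseudocount of 0.1 gave 22, no filter 47 and a replicate block 14. A pseudocount of 10 gave 270 for the difference of the BMP4 effects. The cause was not tested.

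Fits of only the groups compared, with fewer libraries for the spread, gave 48 and 1 genes for OA against ODR at days 6 and 14 and 2 and 4394 for OB against OA at days 1 and 14. They gave 296 for the difference of the BMP4 effects and 1321 for OA from day 1 to day 14. Here limma called 0 genes, beside 1681, 1158, 3060 and 2114 at an unadjusted p below 0.05, for OB against ODR and OA against ODR at day 1, BMP4 in ODR and OB against ODR with BMP4.

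With the shared library in both of its groups, the counts were 69 for OB against ODR at day 1, 477 for OA against ODR at day 14, and 123 for OB against OA at day 1. They were 0 for BMP4 in ODR by limma (1194 at an unadjusted p below 0.05), 1400 for OB against ODR with BMP4 and 263 for the difference of the BMP4 effects. With it in ODR without BMP4 only, OA against ODR at day 6 had 565. With it in ODR with BMP4 only, they were 68, 432 and 115 for the first 3, 146 for OA against ODR at day 6, 5 for BMP4 in ODR and 1330 for OB against ODR with BMP4. In its BMP pathway values the shared library resembles ODR without BMP4, which goes against the placements with BMP4. Without the library labelled OA day 14 replicate 2 in the fit, the counts were 264 for OB against ODR at day 1, 23 and 646 for OA against ODR at days 1 and 6, and 405 and 1625 for OB against OA at days 1 and 6. They were 2466 for BMP4 in ODR, 710 for OB against ODR with BMP4 and 476 for the difference of the BMP4 effects. The spread pooled over groups changes with that library, and the cause was not tested further.

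Without each replicate in turn, the counts ranged from 16 to 134, 520 to 1284 and 6564 to 7225 for OB against ODR at days 1, 6 and 14, from 7 to 17, 28 to 189 and 344 to 1228 for OA against ODR, and from 33 to 174, 542 to 880 and 6030 to 7199 for OB against OA. They ranged from 770 to 985 for BMP4 in ODR, 2514 to 4171 in OB, 57 to 345 for OB against ODR with BMP4 and 46 to 169 for the difference of the BMP4 effects. Over time they ranged from 3874 to 5382 in ODR, 3786 to 5648 in OA and 5430 to 6663 in OB, and 3629 to 4618 for the difference. Where a group was left with 1 library, it was assumed to vary like the others. With an estimated correlation, 2 of 96 list calls and 7 of 21 set calls were left.

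The groups share replicate numbers, which no label ties to a batch. At day 14, the correlation of the residuals of same-number libraries had a median of 0.0887 over 9 pairs, from 0.0318 to 0.316, against -0.0445 for different numbers. Only 4 of the 9 were above 0.1. Every library there correlated best with its own number in each other group, with an exception between OB and OA. Of the libraries of the other group, OB replicate 1 and the library labelled OA day 14 replicate 2 correlated best with each other (0.139). Within ODR, both correlated best with their own number (0.156 and 0.0345). At day 6 the medians were 0.0207 and -0.0187. At day 1, with 2 libraries per group, they were 0.222 and -0.222, the latter fixed by the former. A replicate block gave 7879 genes for OB against ODR at day 14, of which 7440 were among the 7583, and moved only the count of OA against ODR at day 1 by more than 1.5 times. It kept 1039 of the 1461 calls of OB against ODR at day 6, 185 of 308 and 616 of 741 of OA against ODR at days 6 and 14, 1201 of 1598 for BMP4 in ODR, 3675 of 4504 in OB and 97 of 174 for their difference. It left 90 list calls and 19 set calls.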

Other observations

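The tests of persistence and of the BMP4 response against OB at day 14 were written before their results were seen, and the comparison of shared controls was chosen after.

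The day 9 libraries hold further values outside the tests. Id1 was 9301 in both ODDR and ODB without BMP4, where Id3 was 16 and 15. The library under both BMP4 labels had Id1 at 5616, Id2 at 629, Id3 at 623, Smad6 at 184, Msx2 at 200, the hematopoietic and trophoblast factor Gata2 at 474 and Hand1 at 69. Its Kdm2b value was 239, against 18690 in ODB and 452 in ODDR without BMP4, which goes against its ODB label. Between ODB and ODDR, the muscle list had a median of 1.15 (percentile 98.81 among random lists), neural 1.00 (100) and glycolysis 0.83 (100). The interferon median was -0.35 (2.29), senescence-associated secretory -0.83 (0), macrophage and leukocyte -1.14 (0.15) and keratinocyte -1.04 (0.39). Mki67, a proliferation marker, was 2016 in ODB and 924 in ODDR, and Sall4 134 and 4.

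Across genes, the mESC library was most similar to OB day 14 replicate 1 (Pearson r 0.769), and the MEF library to ODR day 1 replicate 2 (0.887). Genes are not independent replicates, and these values carry no test.

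The hypothesis that the OB changes of day 6 persist at day 14 was not borne out at the level set in advance, since 55.4% of the day 6 calls were past the threshold with the same sign at day 14, under the 60% named before. Of 795 genes higher at day 6, 335 were higher at day 14 (223 by chance), and of 666 lower, 475 were lower (178 by chance). Another 170 were called in the opposite direction. Of the 122 calls of day 1, 31 were called with the same sign at day 14 (33.7 by chance).

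BMP4 at day 6 may move OB cells toward their day 14 state. Across genes the BMP4 response in OB correlated with the day 14 difference between OB and ODR with r = 0.213, between the bounds set in advance, so the test does not decide.

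The OB and OA differences from ODR share control libraries, which correlates them by construction. At day 6 their Pearson r across genes was 0.607, against a mean of 0.634 in 20 simulations with shared controls only, and the covariance was 0.266 against 0.101. Both combinations were higher in 116 genes and lower in 71, and opposite in 1. At day 14 r was 0.499 against 0.497 and the covariance 0.383 against 0.0672. The shared calls were 226 higher, 283 lower and 54 opposite. Without the library labelled OA day 14 replicate 2 they were 270, 247 and 81. With all libraries, the highest number of shared calls in a simulation was 0 at both days. In these simulations OB and OA equalled ODR in every gene, so few genes could be called in either. The 0 is therefore no measure for the shared calls. With all libraries, independent calls would give 10.67 higher and 5.862 lower at day 6, and 109.5 and 93.46 at day 14. Shared controls make the calls dependent, so these numbers are no test either.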
